A study of Mus musculus with 18 samples.

How the data were processed

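Colorectal tissue was profiled by RNA sequencing in 18 libraries, 6 in each of 3 groups named Control, GF-AOM and GF-AOMS. AOM is azoxymethane, a carcinogen used to induce colon tumours in mice, and GF stands for germ-free. Per the labels' protocols, the mice were male C57BL/6J animals aged 10 weeks, total RNA came from colon, RNA with an integrity number of at least 7 was used, ribosomal RNA was depleted and the libraries kept strand information. The labels place all libraries in 1 batch. They give 6 mice per group but do not say in words that each library came from a separate mouse, so the p-values measure the spread between these samples.

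The labels carry 2 readings of the groups. Sample characteristics describe Control as SPF (specific pathogen-free) mice with AOM-induced cancer, GF-AOM as germ-free mice given AOM, and GF-AOMS as germ-free mice given AOM and cigarette smoke. The treatment protocol describes the same groups as untreated, AOM, and AOM with smoke, and the growth protocol places the mice in an SPF facility. Under both readings GF-AOMS differs from GF-AOM by smoke. The comparisons of either group with Control have no single stated meaning, so the groups are called by their names.

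Per the submitters' processing notes, featureCounts and DESeq2 were used with build GRCm39. Versions and the aligner are not given in the sources used here. The deposited table holds read counts for 10897 genes in every library, whole numbers per gene per the file headers. The deposited FPKM values (fragments per kilobase of transcript, scaled by sequencing depth) were computed by the authors for the same genes. Where a count was at least 5000, the ratio of count to FPKM was within 1% of the gene's median ratio for 99.9% of values. Every gene had an FPKM of at least 1 in at least 15 of the 18 libraries, so genes expressed in 1 group alone are not analysed here. Of the gene identifiers, 10890 were found in the GENCODE M21 annotation, and 93.14% of those had both ends within 100 bases of it. That annotation is of build GRCm38, so the positions printed below are those of the table and match GRCm38, although the notes name GRCm39.

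Libraries held 48.95 M to 79.23 M counts (M is the prefix mega), with a mean of 56.16 M (SD 7.41 M, n = 18). All 18 libraries were fitted together with edgeR 4.0.16 in R 4.3.3, with TMM scaling, a quasi-likelihood test, 15 residual degrees of freedom and no covariate. Tests were two-sided, and Benjamini-Hochberg adjusted p under 0.05 over all 10897 genes counted as a call. The design set limma on log2(FPKM + 1) as the main test and edgeR if counts were present. They were, so edgeR is the main test and limma 3.58.1 is given as an alternative. CPM values are counts per M counts after TMM scaling, and log2 CPM uses a prior count of 2. The planned filter (FPKM at least 1 in 6 libraries) removed no gene.

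There were 43 fixed gene lists, chosen for germ-free status, azoxymethane tumours, cigarette smoke and cell types of the colorectum, and the 31 with at least 4 measured members were tested. The test was limma's camera with a preset correlation of 0.01, adjusted over the lists of a comparison. It was repeated with an estimated correlation, and fry was run beside it. Terms of Gene Ontology with 10 to 500 genes were tested among the calls by the hypergeometric test, 2655 terms against 9132 annotated genes, and 302 KEGG pathways were tested by camera. Values per library were compared by two-sided exact permutation tests, for which the smallest possible p with 6 against 6 is 0.00216. The exact Wilcoxon test has the same limit, so over 10897 genes it can call none unless far more genes separate the groups than did in any comparison, and its 0 calls say little.

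Genes were named by a rule. It takes up to 10 genes per direction with the largest log2 difference among calls with a mean FPKM of at least 2 in the higher group and values that do not overlap between groups. With fewer than 5 such genes the overlap condition is dropped, and with none the 3 smallest p are given as values that did not pass. The rule adds the 3 members with the smallest p of each list that passes, and 16 fixed genes, of which 10 were measured. Clone names, pseudogenes and immunoglobulin variable segments are counted and not named. Some genes that the rule takes are not reported here and were not replaced, although they stayed in every test. Genes outside the rule are named as chosen after their values were seen. The groups, lists, naming rule, comparisons and first set of alternatives were chosen before the data were examined.

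The alternatives were other tools (limma, exact Wilcoxon test, DESeq2 1.42.0), other scalings, filters and pseudocounts, sample weights, a replicate block, fits of only the groups compared, and leaving out each library. Quantile normalization, rescaling to the same total and array weights were limma fits on log2 FPKM values, so tool and unit changed with them. A colon position term contrasts the libraries with Hoxa13 and Hoxb13 both under 10 CPM with the rest. It was made from the libraries' own values after they were seen, is used as an alternative only and assigns no library to another group. A length slope covariate carries each library's trend of log2 CPM on relative gene length, taken from the ratio of count to FPKM. For each comparison, 100 of the 462 splits of its 12 libraries into groups of 6 were refitted, with the 6 libraries of the remaining group kept in the fit as in the main test. For Control and the other groups, 50 simulations of unchanged groups gave the similarity that shared Control libraries produce alone.

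The pipeline was tested on simulated counts for 10897 genes in which GF-AOMS differed. Between GF-AOMS and GF-AOM it recovered 66% of 100 genes changed 2-fold and 95% of 100 changed 4-fold, with 10 false calls. Between GF-AOMS and Control the shares were 65% and 96%, with 4 false calls. A list shifted by 0.8 was called in that comparison, and 0 of the other 30 lists were. The simulated genes varied independently of each other, and the changed genes of both sizes were present together, which eases the adjusted threshold. The recovered shares therefore do not show how many changed genes would be found where few genes change or where genes vary together. The simulation also does not show how often the list test calls falsely when genes vary together. The p-values rest on the spread between these libraries and cover them only, since the labels do not say that each is a separate mouse. Sequencing reads are not independent molecules, so read depth adds no replicates.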

Results

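Colorectal tissue was sequenced in 18 libraries, 6 each from mouse groups named Control, GF-AOM and GF-AOMS. Azoxymethane (AOM) induces colon tumours in mice, GF stands for germ-free, and the S marks exposure to cigarette smoke. The labels describe Control both as AOM-treated mice with a microbiota and as untreated mice, so what separates it from the other groups is not settled by them. Total counts averaged 57.8 M in Control (SD 11.77 M, n = 6), 57.23 M in GF-AOM (SD 5.382 M, n = 6) and 53.45 M in GF-AOMS (SD 2.424 M, n = 6). Group totals did not differ by an exact permutation test, with adjusted p from 0.326 to 0.939.

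Genes that mark the position along the colon separated the Control libraries from each other. Hoxa13 (chromosome 6, 52257694 to 52260880) lay at 42.0 and 38.7 CPM in Control replicates 1 and 2, and at 0 to 3.05 CPM in Control replicates 3 to 6. All 12 GF libraries lay between 24.7 and 53.5 CPM. Hoxb13 (chromosome 11, 96194316 to 96197447) was at 122.1 and 330.2 CPM in Control replicates 1 and 2, at 2.43 to 2.65 CPM in Control replicates 3 to 6, and at 19.8 to 292 CPM in the GF libraries. Carbonic anhydrase gene Car1 ran the other way, at 5335 to 19170 CPM in Control replicates 3 to 6 and 688.7 and 727.7 CPM in replicates 1 and 2. The Hox13 genes are expressed in the distal colon, so 4 of the 6 Control libraries lack a distal marker that every GF library carries. For lists that passed against Control and most genes named as called there, the value with colon position as a term of the model is given too. The term leaves 2 Control libraries to carry the group, so it cannot separate position from other traits of these libraries. List p-values with the term use the preset correlation, which treats members as nearly independent, and were not computed with an estimated one. The term was chosen after the Hox values were seen and would also remove any true group difference that runs with Hox expression.

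**Figure D1:**
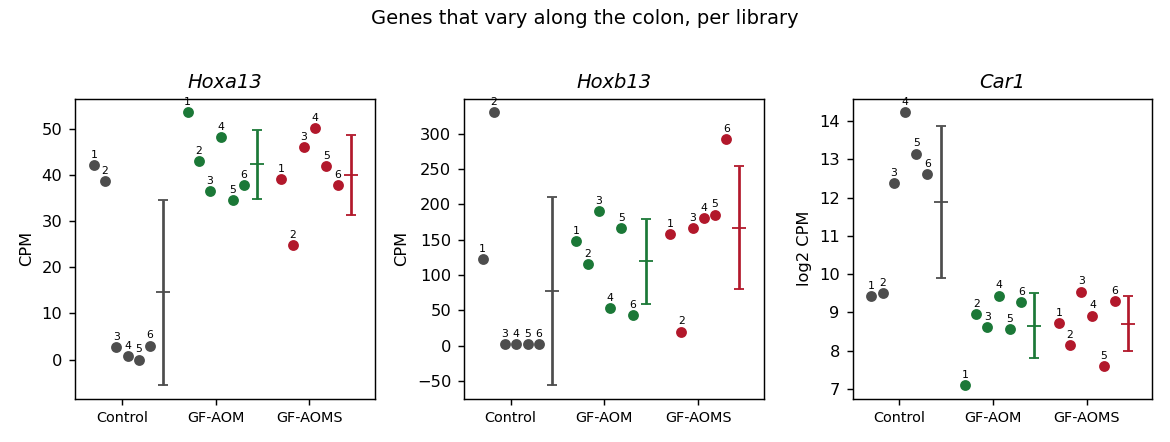
Hoxa13 and Hoxb13 in CPM and Car1 in log2 CPM in each library, with points numbered by replicate and bars giving the group mean ± SD (n = 6). Control replicates 3 to 6 lie at 3.05 CPM or lower for Hoxa13, below all 12 GF libraries, and above all other libraries for Car1.

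Libraries also differed in the share of counts from ribosomal protein genes, which ran from 5.48% to 27.4%. It averaged 8.94% in Control (SD 3.99), 15.2% in GF-AOM (SD 5.13) and 14.4% in GF-AOMS (SD 7.02), n = 6 each. By exact permutation tests GF-AOM against Control gave p = 0.039, adjusted 0.212 over 21 tests of 7 measures, so the difference did not pass. All 86 ribosomal protein genes were higher on average in GF-AOM than in Control (median log2 difference 0.82), and 0 passed. The median was 0.14 with the length slope in the model, with 83 of 86 positive, and 0.39 with colon position. The first principal component held 42.58% of the variance and the next 15.84%. Correlations between libraries were 0.8429 to 0.9812 within groups and 0.8182 to 0.9791 between groups.

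GF-AOM and Control were compared first. This is a contrast of germ-free with colonised tumour-bearing mice under the sample characteristics and of AOM with no AOM under the treatment protocol. Mcf2l was the only gene that passed (ENSMUSG00000031442, chromosome 8, 12873806 to 13020905). It encodes a guanine nucleotide exchange factor and rose from 67.5 ± 9.35 to 103.3 ± 6.91 CPM (SD, n = 6), a log2 difference of 0.61 (SE 0.10, adjusted p = 0.0495), higher in 6 of 6 libraries. Its difference was 0.51 (SE 0.14) with colon position in the model and did not pass. Carbonic anhydrase gene Car1 and carboxylesterase gene Ces2a had the largest differences among the smallest p, at -3.93 and -2.61, and both missed the threshold with an adjusted p of 0.0638. Their differences were -0.65 and -0.85 with colon position in the model.

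Mitochondrially encoded genes lay lower in GF-AOM, with a mean log2 difference of -0.44 over 13 measured members, 12 of them negative, and a list adjusted p of 6.02e-08. The mean was below that of Control in 6 of 6 libraries. With an estimated correlation the adjusted p was 0.453. No member passed over all genes, and 8 were lower adjusted over the list alone, among them mt-Nd2 (-0.59, SE 0.13), mt-Nd4l (-0.69, SE 0.16) and mt-Nd5 (-0.83, SE 0.20). The list kept a mean of -0.36 with colon position in the model (adjusted p = 6.22e-08 at the preset correlation). Counts from the mitochondrial genome made up 4.59% of Control libraries (SD 0.722) and 3.15% of GF-AOM libraries (SD 0.496, n = 6), with an exact permutation p of 0.00649 that did not pass adjustment (0.0681).

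Epithelial metabolism and barrier lists were lower in the same comparison. Fatty acid oxidation and ketogenesis had a mean of -0.60 with 10 of 10 members negative (adjusted p = 1.75e-05, and 0.453 with an estimated correlation). Of these, 7 were lower adjusted over the list alone, with Cpt2 at -0.69 (SE 0.18) and Ehhadh at -0.68 (SE 0.20). Tight and adherens junctions had a mean of -0.42 with 14 of 15 members negative (adjusted p = 4.1e-05, and 0.453 with an estimated correlation), and 5 were lower adjusted over the list alone. Cldn4 was at -1.49 (SE 0.34), Cldn23 at -0.73 (SE 0.22) and F11r at -0.37 (SE 0.11). Bile acid and xenobiotic receptor targets had a mean of -1.16 with 6 of 7 members negative (adjusted p = 0.000654, and 0.453 with an estimated correlation), with 5 of 7 members lower adjusted over the list alone, led by Ces2a, Cyp2c55 (-2.67, SE 0.64) and Cyp3a13 (-1.05, SE 0.31). NRF2 targets had a mean of -0.34 with 12 of 14 members negative (adjusted p = 0.00313, and 0.453 with an estimated correlation), with 2 lower adjusted over the list alone. Ugdh stood at -1.81 (SE 0.37), with Gclm at -0.32 and Srxn1 at -0.48. Absorptive colonocyte markers had a mean of -0.59 but a median of -0.23, with 8 of 12 members negative and Car1 the largest (adjusted p = 0.0445, and 0.524 with an estimated correlation), with 3 of 12 lower adjusted over the list alone, Car1, Cdhr5 (-1.34, SE 0.27) and Ceacam20 (-1.07, SE 0.37). Once colon position was in the model, the means were -0.03 for fatty acid oxidation, -0.25 for junctions, 0.05 for bile acid targets, -0.03 for NRF2 targets and -0.43 for colonocytes. Among their members Cyp2c55 was then at 0.04, Cyp3a13 at -0.22, Ugdh at -0.11, Cldn4 at -0.55 and Cpt2 at -0.33. Ehhadh was at -0.17, Cldn23 at -0.33, Gclm at -0.21, Srxn1 at -0.12 and Cdhr5 at -0.81. F11r at -0.41 and Ceacam20 at -1.51 were no smaller than without the term. Junctions (adjusted p = 0.00122) and colonocytes (0.00113) still passed there, and the others did not. The colonocyte list also no longer passed without Control replicate 1 (mean -0.53), 2 (-0.62) or 4 (-0.46) or without GF-AOM replicate 1 (-0.47) or 2 (-0.61). It was also lost with the length slope (-0.47, adjusted p = 0.0803), with array weights and when only the 2 groups were fitted.

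Immune lists did not share a direction. T and NK cell genes (mean 0.02, adjusted p = 0.667) and MHC class II genes (0.22, adjusted p = 0.22) did not pass. Interferon-stimulated genes had a mean of -0.53 with 14 of 15 members negative (adjusted p = 0.00161, and 0.544 with an estimated correlation), with Rsad2 at -1.12 (SE 0.34), Ifit1 at -1.31 (SE 0.53) and Oasl2 at -0.93 (SE 0.40). Their mean was -0.66 with colon position in the model (adjusted p = 2.15e-06). Plasma cell genes had a mean of 0.79 with 11 of 12 members positive and 6 of 6 libraries above the Control mean (adjusted p = 6.2e-05, and 0.461 with an estimated correlation). Jchain lay at 4745 ± 1410 CPM against 1977 ± 1110 CPM in Control (log2 1.26, SE 0.42), Tnfrsf17 at 1.38 (SE 0.55) and Mzb1 at 1.43 (SE 0.61). Adding colon position to the model brought the plasma cell mean to -0.01, with Jchain at 0.58, Tnfrsf17 at 0.54 and Mzb1 at 0.45. Macrophage and monocyte genes had a mean of 0.40 with 11 of 11 members positive (adjusted p = 0.00327, and 0.544 with an estimated correlation), with Cd14 at 0.45 (SE 0.20), C1qb at 0.56 and C1qc at 0.56. Smooth muscle genes had a mean of 0.33 with 10 of 11 positive (adjusted p = 0.0459, and 0.686 with an estimated correlation), with Tagln at 0.77 (SE 0.44), Cnn1 at 0.66 and Kcnmb1 at 0.32. Neither of the last lists passed with colon position in the model, at 0.22 and 0.06. The macrophage list did not pass without Control replicate 4 (0.25), nor smooth muscle without Control replicate 2 (0.39), 4 (0.23) or 5 (0.22) or GF-AOM replicate 2 (0.36) or 4 (0.20). With the length slope neither passed, at 0.14 for macrophages (adjusted p = 0.116) and 0.08 for smooth muscle (0.892), and smooth muscle was also lost with array weights, quantile normalization and the stricter filter (FPKM at least 5 in 6 libraries). No member of the interferon, plasma cell, macrophage or smooth muscle lists was called, over all genes or over the list alone.

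Across the genome, 1713 genes had an unadjusted p under 0.05 where 544.8 are expected by chance, and 1 passed adjustment. With colon position in the model 344 genes had an unadjusted p under 0.05, fewer than expected by chance. DESeq2 called 284 genes, 69 higher and 215 lower, while limma on FPKM and the exact Wilcoxon test called 0, with 1469 and 1409 genes at an unadjusted p under 0.05. Values of the groups did not overlap for 83 genes, or 0.762% against 0.217% expected by chance. The count depended on single libraries. It was 45 without Control replicate 1, 356 without Control replicate 2, 4 without GF-AOM replicate 4, 1 without GF-AOMS replicate 2, and 0 without any 1 of the other 14. Of the 31 lists tested 10 passed, 3 up and 7 down, 0 with an estimated correlation, and fry called 1. Of 302 KEGG pathways 57 passed, 0 with an estimated correlation, with Ribosome (mean 0.62, adjusted p = 6.08e-15), fatty acid degradation (-0.28) and PPAR signaling (-0.38) at the smallest p.

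Smoke was the question of the comparison of GF-AOMS with GF-AOM, the only contrast with the same meaning under both readings of the labels. No gene passed. The smallest p belonged to Spp1 (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050), which encodes osteopontin, and to the X-linked homeobox gene Rhox5 (ENSMUSG00000095180, chromosome X, 37804842 to 37808876). Spp1 lay at 28.4 ± 10.3 CPM in GF-AOMS and 9.53 ± 3.36 CPM in GF-AOM (SD, n = 6), a log2 difference of 1.57 (SE 0.30, adjusted p = 0.24), with all 6 smoke libraries above all 6 others. Rhox5 lay at 4.65 ± 1.71 and 1.91 ± 0.509 CPM, a difference of 1.28 (SE 0.24, adjusted p = 0.24), also without overlap. Uimc1 (ENSMUSG00000025878, chromosome 13, 55027880 to 55100300), for a subunit of a DNA repair complex, lay at 238.3 ± 121 and 104.2 ± 26.2 CPM, a difference of 1.19 (SE 0.26, adjusted p = 0.82). DESeq2 called these 3 genes and no other, with adjusted p of 0.00093 for Spp1, 0.00093 for Rhox5 and 0.0322 for Uimc1. Over all alternatives the adjusted p ran from 0.00093 to 1 for Spp1 and Rhox5 and from 9.68e-05 to 1 for Uimc1. The smallest p in the other direction belonged to Ramp2 (-1.09, SE 0.31), P2ry13 (-0.80, SE 0.27) and the mitochondrial transfer RNA gene mt-Tr (-0.77, SE 0.27), each with an adjusted p of 1. Counts for mt-Tr were low, at 0.228 CPM in GF-AOM and 0.133 CPM in GF-AOMS.

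Proliferation genes lay higher with smoke. All 20 measured members were positive, with a mean of 0.26 (adjusted p = 7.03e-08, and 0.82 with an estimated correlation), and 4 of 6 libraries lay above the GF-AOM mean. Aurkb stood at 0.51 (SE 0.28), Mcm7 at 0.25 (SE 0.16) and Ccnb2 at 0.37 (SE 0.23). Among KEGG pathways, DNA replication (mean 0.12), cell cycle (0.09) and mismatch repair (0.13) had the smallest adjusted p, and 14 of 302 pathways passed, with 0 when the correlation was estimated. Heat shock genes were positive in 9 of 9 members, with a mean of 0.21 (adjusted p = 0.00184, and 0.605 with an estimated correlation), led by Hspb1 (0.46, SE 0.26), Hsp90aa1 (0.24) and Hspa1b (0.35). Lower lists were macrophages and monocytes at a mean of -0.27 (adjusted p = 0.000392, and 0.82 with an estimated correlation), plasma cells at -0.25 (0.00607, and 0.83) and endothelium at -0.15 (0.014, and 0.82). Among their members Mrc1 was at -0.58 (SE 0.26), Csf1r at -0.36, Cd68 at -0.38, Jchain at -0.57 (SE 0.42), Igkc at -0.41, Iglc2 at -0.51, Emcn at -0.24, Tie1 at -0.25 and Cldn5 at -0.21. Plasma cells did not pass without GF-AOM replicate 2 (-0.09) or GF-AOMS replicate 1 (-0.15) or 4 (-0.16), and heat shock did not without GF-AOMS replicate 6 (0.13). Endothelium did not pass without GF-AOM replicate 1 (-0.04) or 2 (-0.15) or GF-AOMS replicate 1 (-0.14) or 2 (-0.09). Without the 5 libraries with TMM factors under 0.9 these 3 lists did not pass, array weights also lost heat shock and endothelium, and the stricter FPKM filter lost endothelium. No member of these 5 lists passed, over all genes or over the list alone.

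Lists tied most closely to smoke chemistry did not pass. NRF2 targets had a mean of 0.07 with 9 of 14 members positive (adjusted p = 0.0861). Of 8 aryl hydrocarbon receptor targets 3 were measured, too few for the set test, all with small negative differences and a mean of -0.08. Cyp1a1, Cyp1b1 and Ahrr were not analysed here. Ccl2, from the list of inflammatory mediators, was the one member of any fixed list to differ adjusted over the list alone, and it was higher with smoke. That list had 2 of 18 members measured, too few for the set test, and Ccl2 has an adjusted p of 1 over all genes.

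Only 119 genes had an unadjusted p under 0.05 in this comparison, against 544.8 expected by chance, and edgeR called 0. DESeq2 called 3, limma on FPKM 0 (89 at an unadjusted p under 0.05) and the exact Wilcoxon test 0 (145). Values did not overlap for 7 genes, 0.0642% against 0.217% expected by chance. Leaving out any 1 library left the count at 0. Of the 31 lists 5 passed, 2 up and 3 down, and the count rose to 9 without GF-AOM replicate 6, 9 without GF-AOMS replicate 2 and 8 without GF-AOMS replicate 5. Fry called 0.

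**Figure D2:**
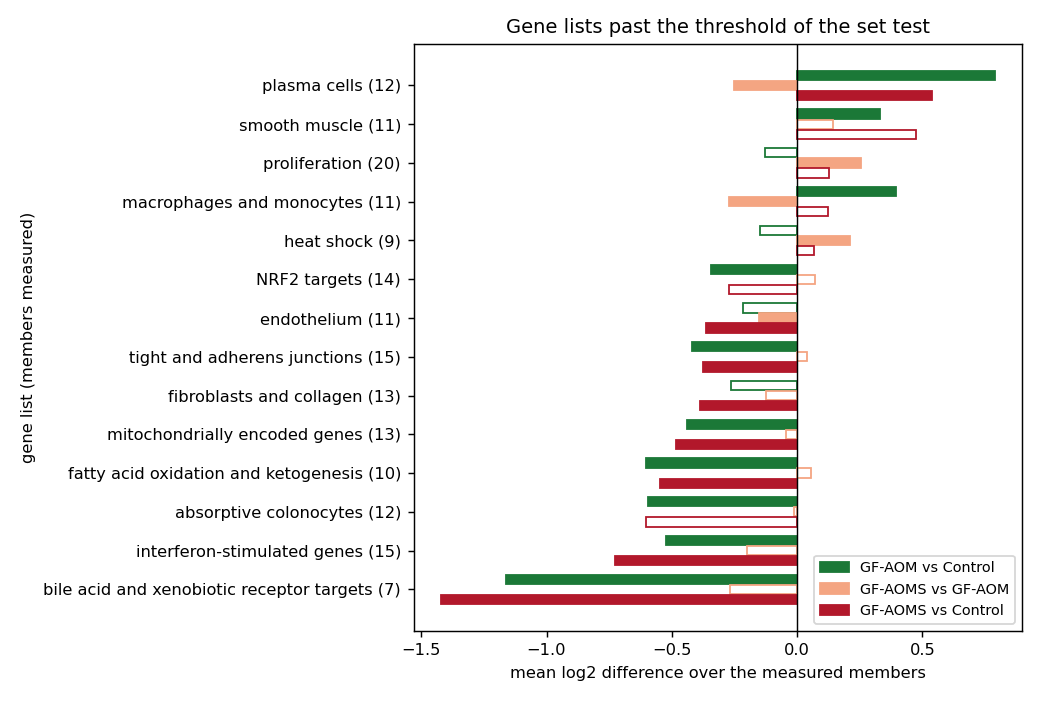
Mean log2 difference over the measured members of each gene list that passed in at least 1 of the 3 comparisons, with filled bars for lists past the threshold of camera at the preset correlation and open bars for lists that were not. Bile acid and xenobiotic receptor targets reach -1.42 in GF-AOMS against Control and plasma cells 0.79 in GF-AOM against Control.

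GF-AOMS and Control differed in 80 genes, 12 higher and 68 lower. Spp1 rose to 28.4 CPM from 9.45 ± 3.68 CPM in Control (SD, n = 6; log2 1.59, SE 0.30, adjusted p = 0.0304), Uimc1 to 238.3 from 84.1 ± 20.2 CPM (1.5, SE 0.262) and Rhox5 to 4.65 from 2.01 ± 0.291 CPM (1.21, SE 0.24). Each was higher in 6 of 6 libraries. The corresponding differences of GF-AOM from Control were 0.01, 0.31 and -0.07. The 3 differences from Control were 1.62, 1.28 and 1.43 with colon position in the model, with none past the threshold. Rab32 (0.97, SE 0.19), Mcub (0.88, SE 0.19), Inf2 (0.59, SE 0.13), Mcf2l (0.45, SE 0.10) and Ccdc22 (0.40, SE 0.09) also rose. In that model Rab32 was at 0.38, Mcub at 0.65, Inf2 at 0.40, Mcf2l at 0.34 and Ccdc22 at 0.51. Rab32 lay at 42.1 ± 3.44 CPM against 21.5 ± 8.47 CPM in Control and was already at 40.4 ± 6.48 CPM in GF-AOM. Among the other risen genes, Rbm3 and its pseudogene share sequence, so their reads cannot be assigned to either with certainty.

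Among the genes that fell without overlap between groups, Ces2a, Ces2c and Chga had the largest differences. Ces2a (ENSMUSG00000055730, chromosome 8, 104734003 to 104741634) fell to 11.33 ± 2.498 CPM from 78.96 ± 61.54 CPM (-2.80, SE 0.47, adjusted p = 0.0304) and Ces2c to 62.1 ± 15.5 CPM from 251 ± 150 CPM (-2.02, SE 0.36). These paralogs can share reads. Chga, for chromogranin A, fell to 25.6 ± 6.03 CPM from 100.8 ± 66.3 CPM (-1.98, SE 0.36). Apol7a (-1.72), Rsad2 (-1.62), H2-Q1 (-1.41), Prss30 (-1.28), Gramd3 (-1.01), Nudt4 (-0.999) and Tsc22d1 (-0.91) followed, all lower in 6 of 6 libraries without overlap. Allowing for colon position, Ces2a was at -1.03, Ces2c at -0.87, Chga at -0.61, Apol7a at -1.09, Prss30 at -0.76, Gramd3 at -0.43, H2-Q1 at -0.36, Tsc22d1 at -0.30 and Nudt4 at -0.23, while Rsad2 was at -1.81 (SE 0.45). Prap1 (-4.13), Car1 (-3.91), the transporter gene Abcb1a (-2.17), lipoprotein lipase gene Lpl (-2.03), Chgb (-1.88) and Duox2 (-1.44) were among the others that fell, and are named here after their values were seen. Their differences allowing for colon position were -0.44 for Prap1, -0.63 for Car1, -0.81 for Abcb1a, -0.27 for Lpl, -0.62 for Chgb and -0.79 for Duox2. Lower calls were enriched in carboxylic ester hydrolase activity, with 6 genes where 0.207 are expected (adjusted p = 0.000118), namely Ces2a, Ces2c, Ces2e, Lpl, Nceh1 and Bche. Lipid catabolic process (6 genes, adjusted p = 0.00239) and triglyceride lipase activity (4 genes, 0.00239) also passed among 2655 terms, and no term passed among higher calls. Of 11 adipocyte markers 3 were measured, too few for the set test. All 3 were lower (mean -1.6), with 0 called over all genes and 1 lower adjusted over the list alone. With colon position in the model Cidec went from -2.09 to 0.08 and Cfd from -2.04 to 1.89. These members are named after their values were seen, and the value of the other member is not given here.

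**Figure D3:**
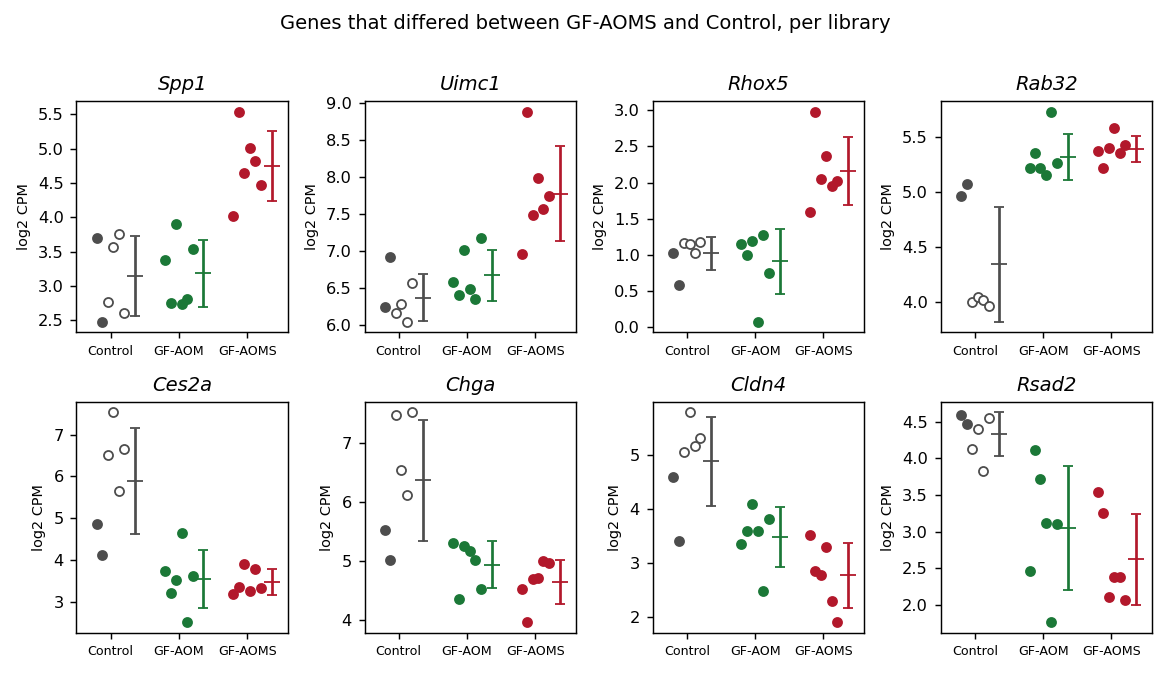
Log2 CPM in each library of 8 genes that differed between GF-AOMS and Control, with group mean ± SD (n = 6) at the right of each group and open circles for Control replicates 3 to 6, the libraries without distal colon markers. For Spp1, Uimc1 and Rhox5 every GF-AOMS library lies above every Control library, and for Rab32, Ces2a and Chga the open circles lie farther from the GF groups than the filled Control circles.

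Mitochondrially encoded genes had a mean of -0.48 in GF-AOMS against Control, with 12 of 13 members negative and 6 of 6 libraries below the Control mean (adjusted p = 1.44e-09, and 0.435 with an estimated correlation). Of these mt-Nd2 fell (-0.62, SE 0.13, adjusted p = 0.0408), and 8 were lower adjusted over the list alone, including mt-Nd5 (-0.85) and mt-Nd4l (-0.68). The mean was -0.40 with colon position in the model (adjusted p = 4.91e-10), and mt-Nd2 was at -0.60. Interferon-stimulated genes had a mean of -0.73 with 13 of 15 negative (adjusted p = 3.4e-05, and 0.567 with an estimated correlation). Rsad2 fell, and 5 members were lower adjusted over the list alone, with Ifit1 at -2.13 (SE 0.54) and Oasl2 at -1.48 (SE 0.40). Their mean with colon position was -0.86. Duox2 was the called member of the list of microbe-responsive epithelial defence, which did not pass (mean -0.11, adjusted p = 0.614). Enteroendocrine markers held 2 called genes, Chga and Chgb, and did not pass either (mean -0.69, adjusted p = 0.217).

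Bile acid and xenobiotic receptor targets had a mean of -1.42 with 7 of 7 members negative (adjusted p = 6.24e-05, and 0.435 with an estimated correlation). Ces2a and Cyp2c55 fell, Cyp2c55 (ENSMUSG00000025002, chromosome 19, 39007019 to 39042693) from 1462 ± 1207 to 110.2 ± 57.3 CPM (-3.73, SE 0.67, adjusted p = 0.0304), and 5 members were lower adjusted over the list alone, including Cyp3a13 (-1.30). Junction genes had a mean of -0.38 with 13 of 15 negative (adjusted p = 0.000231, and 0.564 with an estimated correlation). Cldn4 fell from 33.07 ± 15.03 to 7.304 ± 2.883 CPM (-2.18, SE 0.35, adjusted p = 0.0304), and 3 were lower adjusted over the list alone, including Cldn23 (-0.93) and F11r (-0.38). Fatty acid oxidation had a mean of -0.55 with 9 of 10 negative (adjusted p = 0.000231, and 0.567 with an estimated correlation), with 6 lower adjusted over the list alone, among them Ehhadh (-0.64). The means were, with colon position in the model, -0.22 for bile acid targets, -0.21 for junctions and 0.02 for fatty acid oxidation. Only junctions still passed there (adjusted p = 0.00421), and they did not with the length slope (-0.22, adjusted p = 0.105). Allowing for colon position, Cyp2c55 was at -1.02 and Cldn4 at -1.24.

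Endothelium and fibroblast lists were lower and plasma cells higher in GF-AOMS than in Control, while smooth muscle did not pass (mean 0.48 with 10 of 11 positive, adjusted p = 0.0619). Endothelium had a mean of -0.37 with 9 of 11 negative (adjusted p = 0.000785, and 0.564 with an estimated correlation), with 1 member lower adjusted over the list alone, Emcn (-0.64, SE 0.17), beside Tek (-0.70) and Eng (-0.43). Fibroblast and collagen genes had a mean of -0.39 with 12 of 13 negative (adjusted p = 0.00587, and 0.571 with an estimated correlation), with Col1a1 at -0.83 (SE 0.26), Postn at -0.70 and Col1a2 at -0.58 and 0 members past any threshold. Their means with colon position were -0.31 and -0.31, and both passed, but endothelium did not with the stricter FPKM filter. Plasma cell genes had a mean of 0.54 with 11 of 12 positive (adjusted p = 0.00861, and 0.661 with an estimated correlation), with Mzb1 at 1.28, Tnfrsf17 at 0.99 and Jchain at 0.70 and 0 past any threshold. Allowing for colon position, the plasma cell mean was -0.26 and passed in the other direction (adjusted p = 0.0205 at the preset correlation). The named members did not turn negative there, with Mzb1 at 0.30, Tnfrsf17 at 0.15 and Jchain at 0.01. Without Control replicate 4 (0.33) or GF-AOMS replicate 3 (0.34) the list did not pass, nor did it with the length slope (0.31, adjusted p = 0.149) or array weights.

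In all, 1763 genes had an unadjusted p under 0.05 in GF-AOMS against Control, and values did not overlap for 87 genes, 0.798% against 0.217% expected by chance. Of the 80 calls, 32 were among them. DESeq2 called 375 genes including all 80. Limma on FPKM called 19 (9 higher, 10 lower), 16 of them shared, and the exact Wilcoxon test called 0 with 1133 genes at an unadjusted p under 0.05. The share of lower calls was 85% with edgeR and 67.9% with edgeR without TMM scaling. With limma on FPKM it was 52.6%, and 65.6% after quantile normalization and 55.6% after rescaling FPKM to the same total. Colon position as a term left 0 calls with edgeR and 350 genes at an unadjusted p under 0.05. The count was 493 without Control replicate 2, 16 without Control replicate 5, 34, 31, 40 and 39 without GF-AOM replicates 2, 3, 5 and 6, 2 without GF-AOMS replicate 1 and 51 without GF-AOMS replicate 3. It was 0 without Control replicate 3, 4 or 6 and without GF-AOMS replicate 2, 4, 5 or 6. Of 31 lists 8 passed, 1 up and 7 down, 0 with an estimated correlation, and fry called 2. Of 302 KEGG pathways 29 passed, 0 with an estimated correlation, among them Ribosome (mean 0.62, adjusted p = 1.29e-12) and PPAR signaling (-0.40, adjusted p = 0.000368).

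None of the 10 measured fixed genes passed in any comparison. The antimicrobial lectin genes Reg3g and Reg3b varied more within groups than between them, with Reg3g at 63.5 ± 86.6, 49.6 ± 59.4 and 50.2 ± 36.6 CPM in Control, GF-AOM and GF-AOMS and Reg3b at 201.5 ± 287, 173.3 ± 329 and 165.7 ± 165 CPM (SD, n = 6). Their differences from Control were -0.36 and -0.34 for Reg3g and -0.22 and -0.28 for Reg3b, and changed sign with colon position in the model. Igha, for the constant region of immunoglobulin A, lay at 3762 ± 1953, 5539 ± 2438 and 4197 ± 3469 CPM. With smoke, Mki67 differed by 0.36 (SE 0.31), Axin2 by 0.08 (SE 0.30), Il1b by 0.68 (SE 0.49), Nqo1 by -0.05 (SE 0.27), Muc2 by -0.30 (SE 0.26) and Slc26a3 by 0.09 (SE 0.40), each with an adjusted p of 1. Against Control in GF-AOMS, Muc2 differed by -0.73 (SE 0.26, adjusted p = 0.197) and Il1b by 1.34 (SE 0.49, adjusted p = 0.212), and by -0.23 and 1.13 allowing for colon position.

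Differences of GF-AOM and GF-AOMS from Control resembled each other. Across genes, which are not independent replicates, their correlation was 0.896 where unchanged groups sharing the Control libraries give 0.502. The covariance was 0.147 against 0.0368 in those simulations, and 85.7% of genes had the same sign against 66.7%. With the Control libraries split so that neither comparison shared any, the correlations were 0.60 and 0.51 and the covariances 0.109 and 0.0968. The simulations held no difference in colon position, and every set of split Controls included libraries low in Hoxa13 and Hoxb13. A position difference shared by both comparisons would also raise these values, so they cannot show a shared effect of the groups. Mcf2l was the 1 gene called in both.

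Among lists that did not pass, mean, median and test differed in sign for a few. In GF-AOM against Control these were p53 targets (mean -0.02, median 0.11, test upward) and red blood cells (mean 0.09, median 0.09, test downward). With smoke they were absorptive colonocytes (mean -0.01, median 0.08, test upward), smooth muscle (0.15, 0.12, downward), small intestine (0.06, 0.07, downward) and hypoxia (-0.03, -0.03, upward). ERK feedback genes had a mean of -0.003 and a median of 0.004 with an upward test. In GF-AOMS against Control they were T and NK cells (mean -0.02, median 0.14, test upward) and red blood cells (0.18, 0.17, downward).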

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

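Which library stood apart from the other 5 of its group was tested with Dixon's ratio, set before the data were examined, while the study group test of the first component and the germ-free state test of plasma cells were chosen only after the result was seen. Of 306 groups of 6 values, 22 had a ratio over 0.625, where 15.3 are expected by chance at 1 in 20. All libraries were kept. Values below are log2 CPM.

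GF-AOMS replicate 2 stood apart in 7 groups. It was highest for Mzb1 (8.43 against 5.54 to 6.18, ratio 0.778), C1qb (7.61 against 6.20 to 6.51, ratio 0.778) and C1qc (7.28 against 5.86 to 6.26, ratio 0.72). It was lowest for F11r (6.43 against 7.03 to 7.17, ratio 0.805), Tek (2.06 against 3.19 to 3.73, ratio 0.679), the endothelium list (3.88 against 4.28 to 4.51, ratio 0.629) and Hoxb13 (4.31 against 7.30 to 8.19, ratio 0.771). It also had the highest ribosomal protein share of all libraries, 27.4%, and the lowest TMM factor, 0.721. Without it 0 genes were called between GF-AOMS and Control.

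Control replicate 3 was lowest for the Y-linked gene Ddx3y (0.195 against 4.80 to 5.64, ratio 0.847), at 1.11 CPM where the other Control libraries had 27.9 to 49.8 CPM. Uty (0.555 CPM) and Eif2s3y (1.02 CPM) were equally low there, although the labels give male mice. A female or mixed-up animal could give such values, and the cause was not tested. Without this library 0 genes were called between GF-AOMS and Control.

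Control replicate 2 was lowest for Rhox5 (0.573 against 1.02 to 1.17, ratio 0.739) and the junction list (6.52 against 6.84 to 6.92, ratio 0.806). It was highest for the share of counts from ribosomal RNA loci (1.82% against 0.517% to 0.975%, ratio 0.648). Without it 493 genes were called between GF-AOMS and Control. Control replicate 4 was highest for Gclm (6.93 against 6.48 to 6.64, ratio 0.651) and lowest for Iglc2 (3.14 against 5.49 to 5.88, ratio 0.855).

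In GF-AOM, replicate 1 was lowest for Car1 (7.09 against 8.57 to 9.44, ratio 0.63) and highest for mt-Nd5 (10.1 against 9.28 to 9.49, ratio 0.75) and Tie1 (5.16 against 3.66 to 4.21, ratio 0.637). Replicate 2 was highest for Igha (13.3 against 11.9 to 12.3, ratio 0.706), Col1a1 (6.74 against 5.73 to 6.10, ratio 0.631) and Col1a2 (7.72 against 6.90 to 7.08, ratio 0.779). Replicate 4 was highest for the fatty acid oxidation list (7.22 against 6.50 to 6.65, ratio 0.802), and replicate 5 for Rab32 (5.73 against 5.15 to 5.35, ratio 0.653). In GF-AOMS, replicate 3 was highest for Igha (13.5 against 10.9 to 11.8, ratio 0.653).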

How the results depend on the processing

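Settings chosen only after the result was seen were DESeq2, scaling without TMM, the colon position term, the length slope covariate and the fit without the 5 libraries with TMM factors under 0.9, as well as the study group test of the first component and the germ-free state test of plasma cells. Limma on log2(FPKM + 1) was set beforehand as the main test and became an alternative once counts were found. The other settings were set before the data were examined.

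Between GF-AOM and Control 1 gene was called. The count was 0 with limma on log2(FPKM + 1) or log2(FPKM + 0.1), with log2 differences of at least 1, with the exact Wilcoxon test, without TMM factors, after rescaling all libraries to the same total and when only the 2 groups were fitted. It was 284 with DESeq2, 747 with array weights, 2 with a replicate block, neither of them Mcf2l, and 132 without the 5 libraries of low TMM factor. Mcf2l kept a log2 difference of 0.397 to 0.666 over all alternatives, with adjusted p from 3.07e-07 to 1, and was called in 12 of 34. The position term called 1 gene, which was Tef and not Mcf2l. Leaving out 1 library gave 45 calls without Control replicate 1, 356 without Control replicate 2, 4 without GF-AOM replicate 4, 1 without GF-AOMS replicate 2 and 0 in the other 14 cases.

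Between GF-AOMS and GF-AOM 0 genes were called, and leaving out any 1 library kept it at 0. DESeq2 called 3, array weights 6, the length slope covariate 2 and the fit without the 5 libraries of low TMM factor 1, which was Uimc1. Over all alternatives Spp1 differed by 1.38 to 1.80 and was called in 2 of 34, Uimc1 by 0.879 to 1.33 (4 of 34) and Rhox5 by 0.929 to 1.38 (2 of 33).

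Between GF-AOMS and Control 80 genes were called. The count was 375 with DESeq2, 906 with array weights and 277 without the 5 libraries of low TMM factor. It was 47 with log2 differences of at least 1, 32 after quantile normalization, 28 without TMM factors, 20 with limma on log2(FPKM + 0.1), 19 with limma on log2(FPKM + 1), 9 after rescaling to the same total and 6 with the length slope. It was 0 with the position term, with the exact Wilcoxon test and when only the 2 groups were fitted. Without 1 library the count was 493 (Control replicate 2), 97 (Control 1), 16 (Control 5), 54, 34, 31, 61, 40 and 39 (GF-AOM 1 to 6), 2 (GF-AOMS 1) and 51 (GF-AOMS 3). It was 0 without Control 3, 4 or 6 and without GF-AOMS 2, 4, 5 or 6. All 21 named genes called here kept their direction in every alternative that gave a value for them. Spp1 was called in 20 of 34, Uimc1 in 23 of 34 and Rhox5 in 18 of 33.

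Limma on FPKM rescaled to the same total gave a median log2 difference of all genes of -0.181 in GF-AOM and -0.12 in GF-AOMS against Control. The medians were -0.0784 and -0.0507 with limma on log2(FPKM + 1). The share of lower calls in GF-AOMS against Control was 85%, and 47.7% with array weights (474 higher, 432 lower), 76.5% with DESeq2 and 50% with the length slope. Why the settings differ was not tested.

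Replicate numbers were fitted as a block although they do not pair the libraries. Libraries of the same number correlated at -0.0452 on average over 18 pairs (lowest -0.619, highest 0.517), and 4 of 18 libraries correlated best with one of their own number. The block gave 33 calls between GF-AOMS and Control and 0 between GF-AOMS and GF-AOM.

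Gene lists numbered 10, 5 and 8 in GF-AOM against Control, GF-AOMS against GF-AOM and GF-AOMS against Control, and 0, 0 and 0 with the correlation estimated per list. Between GF-AOMS and GF-AOM 8 lists passed with FPKM of at least 5 and 8 with array weights. Between GF-AOMS and Control 13 passed without the 5 libraries of low TMM factor. Without 1 library the counts were 8 to 14, 4 to 9 and 7 to 12. With smoke they reached 9 without GF-AOM replicate 6, 9 without GF-AOMS replicate 2 and 8 without GF-AOMS replicate 5. With the position term the plasma cell mean reversed to -0.00856 in GF-AOM and -0.259 in GF-AOMS against Control. The 32 other settings and omissions all used the preset correlation. Among them proliferation and macrophages passed in 32 with smoke, heat shock in 29, plasma cells in 28 and endothelium in 25. Interferon-stimulated and mitochondrially encoded genes passed in 32 against Control in both groups. With array weights the endothelium mean in smoke turned positive while the test still pointed down (adjusted p = 0.523). The correlation of the 2 differences from Control was 0.896, and 0.6 and 0.508 with Controls split.

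Genes that turned direction were all uncalled. Reg3g in GF-AOM against Control was 0.133 with limma on log2(FPKM + 1), 0.199 on log2(FPKM + 0.1), 0.0811 after rescaling, 0.105 after quantile normalization, 0.354 with array weights, 0.0831 with the block, 3.11 with the position term and 0.296 by the Wilcoxon setting. Reg3g in GF-AOMS against Control was, in the same order, 0.718, 0.921, 0.768, 0.688, 0.443, 1.36, 3.12 and 1. Reg3b in GF-AOM against Control was 0.161 with limma on log2(FPKM + 1), 0.204 on log2(FPKM + 0.1), 0.0871 after rescaling, 0.0442 after quantile normalization, 4.34 with the position term and 0.297 by the Wilcoxon setting. Reg3b in GF-AOMS against Control was 1.09, 1.17, 1.07, 0.94, 4.27 and 1.23 in that order, 0.434 with array weights and 1.67 with the block. Reg3b with smoke was 0.934, 0.964, 0.985 and 0.896 in the first 4 of these settings, 0.504 with array weights, 1.81 with the block, 0.936 by the Wilcoxon setting, 0.331 with the length slope and 0.832 without the 5 libraries of low TMM factor.

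Mki67 in GF-AOMS against Control was -0.097 with limma on log2(FPKM + 1), -0.13 on log2(FPKM + 0.1), -0.177 after rescaling, -0.0257 after quantile normalization, -0.0189 with the block and -0.0699 by the Wilcoxon setting. Igha there was -0.0339 after rescaling, -0.108 after quantile normalization, -0.0285 with array weights and -0.203 with the position term. The length slope turned Mki67 (0.0764) and Axin2 (0.0119) in GF-AOM against Control and Axin2 with smoke (-0.028). Array weights turned Tie1 with smoke (0.0521), and rescaling turned Nqo1 with smoke (0.00657). The position term turned, in GF-AOM against Control, Cyp2c55 (0.0392), Cnn1 (-0.0115), Kcnmb1 (-0.0184), Nqo1 (0.526), Muc2 (0.0761) and Slc26a3 (-0.0762), and in GF-AOMS against Control Nqo1 (0.478).

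Leaving out 1 library turned the direction of uncalled genes only. With smoke the ranges were -0.0646 to 0.237 for Axin2, -0.153 to 0.0565 for Nqo1, -0.774 to 2.08 for Reg3b, -0.461 to 0.853 for Reg3g, -0.037 to 0.315 for Slc26a3 and -0.335 to 0.0226 for Tie1. In GF-AOM against Control they were -2.36 to 0.453 for Reg3b, -1.18 to 0.426 for Reg3g and -2.44e-05 to 0.611 for Slc26a3. In GF-AOMS against Control they were -0.427 to 0.364 for Igha, -0.229 to 0.224 for Mki67, -0.973 to 0.388 for Reg3b and -0.809 to 0.445 for Reg3g.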

Other observations

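Genes in the next 2 paragraphs were chosen after their values were seen, as were the study group test of the first component and the germ-free state test of plasma cells. Mast cell protease genes Mcpt1 and Mcpt2 lay highest in GF-AOMS, Mcpt1 at 9.29 ± 8.34, 22.2 ± 40.5 and 78.6 ± 79.8 CPM and Mcpt2 at 3.78 ± 2.78, 9.99 ± 15.8 and 41.7 ± 46.7 CPM in Control, GF-AOM and GF-AOMS (SD, n = 6). In GF-AOMS against Control the log2 differences were 3.08 (SE 1.1, adjusted p = 0.199) for Mcpt1 and 3.46 (SE 1.06, adjusted p = 0.129) for Mcpt2. Both were higher adjusted over the list alone, which has 2 of 8 mast cell markers measured. DESeq2 gave adjusted p of 0.0576 and 0.0187, and the differences were 2.37 and 2.68 with the position term. The 2 paralogs can share reads. The chemokine gene Ccl2 lay at 7.89 ± 3.91 CPM in GF-AOMS and 2.54 ± 1.63 CPM in GF-AOM (log2 1.64, SE 0.40, adjusted p = 1, and 0.112 with DESeq2). It was among the 6 genes called there with array weights.

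Resistin-like gene Retnlb lay at 2499, 6620 and 7372 CPM in Control, GF-AOM and GF-AOMS (1.41 and 1.56 against Control, adjusted p 0.31 and 0.261). Its differences were 0.601 and 0.756 with the position term and 0.393 and 0.357 with the length slope. The fat droplet gene Cidec lay at 23.8 ± 21.5 CPM in Control and 5.58 ± 1.45 and 5.60 ± 3.61 CPM in the others (-2.09 in both, adjusted p 0.0987 and 0.0793). DESeq2 called it in both, with adjusted p of 0.00575 and 0.00453. Its differences were 0.0792 and 0.0808 with the position term. Variable segments of immunoglobulin genes, 140 in all, were higher in GF-AOM than in Control for 99 (median log2 0.609) and in GF-AOMS for 93 (0.425), with 0 called by edgeR. With the position term 84 and 74 were higher (medians 0.298 and 0.102).

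The calls between GF-AOMS and Control may in part reflect where along the colon the Control pieces were taken. With the position term the median difference of the 80 genes, aligned to its direction, went from 1.27 to 0.483, or 0.38 of its value (quartiles 0.31 to 0.808), with 77 of 80 keeping their direction, 40 at an unadjusted p under 0.05 and 0 called. Keeping only Control replicates 1 and 2 gave 0.481, which is nearly the same contrast as the position term and no separate support. This value was the lowest of 15 pairs of Controls, where the others gave 0.855 to 1.6. A shift of short transcripts between libraries explains less, since the length slope left 0.811 of the median (1.03) and 80 of 80 directions, although only 4 of the 80 were still called. Chance seldom gave so many calls, with 2 of 100 splits reaching 80, the real one included. That share was not adjusted over the comparisons, and the other such split called 2220, which points to a structure of the samples. The count was also 0 in 7 of 18 fits without 1 library, so chance is not excluded.

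Splits of the other comparisons differ. For genes between GF-AOM and Control 3 of 100 splits reached the 1 real call, and the highest other had 243, which points to a structure of the samples. By that count chance seldom gave a call, but the count was not adjusted over the comparisons and does not exclude chance. The single call, Mcf2l, has an adjusted p of 0.0495. With only the 2 groups fitted 0 genes were called, as in 14 of 18 fits without 1 library. The fits that called any gene left out Control replicate 1 (45), Control replicate 2 (356), GF-AOM replicate 4 (4) or GF-AOMS replicate 2 (1). Between GF-AOMS and GF-AOM the real count is 0, which all 100 splits reach by construction, so the splits decide nothing there. The highest other split had 3643 calls, which points to a structure of the samples. For gene lists 36, 73 and 51 of 100 splits reached the real 10, 5 and 8 in GF-AOM against Control, GF-AOMS against GF-AOM and GF-AOMS against Control. The highest others had 17, 15 and 14, so chance cannot be excluded for any list count.

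The first principal component could follow ribosomal protein transcripts, a trend with transcript length or study group. Without 856 ribosomal protein genes and pseudogenes it correlated at 0.996 with itself and still held 37.3% of the variance. Without the length trend it correlated at 0.997 (35.37%), so it needs neither those genes nor a linear length trend. These tests cannot exclude a difference between whole libraries that the remaining genes also carry. The highest library, GF-AOMS replicate 2 (69.3), had the lowest length slope (-0.306). The lowest, Control replicate 5 (-48.4), had the highest length slope (0.194). Groups held 22.63% of the component's variance (permutation p = 0.146 over 100000 permutations), which cannot tell whether group matters. Of its 200 most weighted genes, 75 were ribosomal protein genes or their pseudogenes, 37.5% against 1.84% of all genes, so this class follows the component closely without being needed for it.

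Plasma cell genes were higher in both GF groups at the preset correlation, but did not pass with an estimated one (adjusted p 0.461 and 0.661). Such a difference could reflect colonisation at collection or colon position. Germ-free mice would be expected to have fewer plasma cells, so a higher score would argue against germ-free colons. The score differed by 1.04 between GF-AOM and Control (95% interval 0.113 to 1.97 with the spread of all 3 groups, and -0.147 to 2.23 with that of the 2 groups alone), and by -0.118 with the position term (-1.11 to 0.878), which cannot tell. The list mean was -0.00856 with the position term, which could come from colon position or from other traits of Control replicates 1 and 2. Tissue from matched positions along the colon, with stool tested for bacteria, would separate these.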
